A study of Homo sapiens with 7 samples.

How the data were processed

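RNA of 7 tumours was measured on Affymetrix arrays with 54675 probe sets, 3 from the arm with continued estrogen (E2) and 4 from tumours growing again after estrogen withdrawal with tamoxifen (TamR). Per the labels' protocols, total RNA was extracted with Trizol and an automated kit, and biotinylated cRNA was made by the standard Affymetrix procedure. The protocol text of TamR 2 words these steps differently from the other 6 arrays. The labels call the arrays biological replicates, so p-values measure the spread between tumours of an arm.

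The deposited values are linear intensity values, 1 per probe set and array. The method of background correction, probe summary and scaling is not given in the sources used here. The array medians were 21.6 to 24.6. The values are linear and not centred by gene, and how the arrays were scaled to each other stays unknown. All arrays share a lowest value of 2.99, and 4.63% to 6.06% of probe sets sit at it. The table holds no detection calls, so a value at the floor described next is only an upper bound.

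Values below 16 were set to 16 and log2 was taken, with no further scaling. At or below this floor lay 35.9% to 40.1% of probe sets per array. Where 1 or more arrays of the dimmer arm lie at the floor, the fold is a lower bound computed with those arrays at the floor and is written as at least N-fold, and the order among such genes is not known. Probe sets were named through the platform annotation given for this table, whose symbols were looked up by gene identifier in the GRCh38.p14 RefSeq table, with 0 symbols changed. That table was used for names and gene order only. A single symbol was given for 41091 probe sets, several for 1801 and none for 11721, and 62 were controls. Probe sets with several or no symbols were not used. Each of the 19775 named genes was read by its probe set of highest mean over all 7 arrays. Genes whose probe set lay below the 40th percentile of means (an intensity of 18.8) were not tested, which left 14241 genes. Among called genes, 531 had several bright probe sets, and for 0 of these did another probe set pass limma's test, run over every probe set, in the opposite direction.

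The arms were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided, arm as the only term). P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p below 0.05 was called. Differences are TamR minus E2 on the log2 scale. With 5 residual degrees of freedom, the number of arrays limits the precision. Lists of genes, 19 for processes and 7 for markers of other cell types, were tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists, again with an estimated correlation, and with fry, which asks whether the members of a list move one way and does not compare them with other genes. With an estimated correlation, the call of the estrogen-repressed list held and the calls of the estrogen-induced list and of the cell cycle list did not. Some members of the estrogen-induced list are also members of the ERK, insulin-like growth factor and coregulator lists.

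The lists, the tests, the settings and the genes to be named were fixed before the data were examined. Named were the 12 genes with the largest difference in each direction among called genes whose arms did not overlap, up to 4 members of each list by smallest p, and ESR1, PGR, TFF1, GREB1, EGFR, ERBB2, IGF1R and MKI67. AGR2, COL3A1, TFF3, FOXA1, TWIST1 and the histone, CEACAM, PSG, HOXC, ALCAM and FKBP5 genes of the closing observations fall outside this rule and were named after their values were seen. AREG, STAT1, CA9, AR, HMGCR and further listed genes were not analysed, since no probe set carried their symbol alone in the annotation used here. Some named members lay below the filter and were not tested either.

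The procedure was tested on simulated arrays with the means and spread of the real ones (14241 genes, 5 draws, 200 genes changed per draw). It recovered 17.6% of genes changed 1.5-fold, 60% of those changed 2-fold and 94.2% of those changed 4-fold, and 3.8% of its calls were false. A list whose members were all lowered 2-fold was called in 5 of 5 draws, and 0 of 125 unchanged lists were called by camera. Genes were drawn independently there, while the estimated correlation in the real estrogen-induced list was 0.283. The simulation therefore does not show how often camera calls unchanged lists whose members move together. Nor does it show how often smaller or mixed shifts of a list are found. The simulated values were not cut at the floor, so the recovered shares may not hold for genes near it. Alternatives were quantile normalisation, median centring, floors of 1 and 64, no filter and a 60th percentile filter, the mean of all probe sets of a gene, every probe set on its own, no trend, a robust fit, array weights, each array left out, the replicate number as a block, and thresholds of 2-fold or of an adjusted p of 0.10. Added after the data were seen were fits with the labelling batch as a block, fits within each batch, the ACTB 3′ to 5′ ratio as a covariate, and the no-filter and floor-of-64 settings without a trend. A further 9 gene families were tested with camera and adjusted over these 9, and were chosen after the data were seen. Batches were read from the dap control probe sets (mean log2 above 5). Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.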

Results

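Gene expression was measured with Affymetrix oligonucleotide arrays in tumours that MCF-7 cells formed in mice. MCF-7 is an estrogen receptor-positive human breast cancer cell line whose growth depends on estrogen. The cells were placed under the skin of ovariectomised nude mice that carried estrogen pellets (0.25 mg, 21-day release), and tumours of 150 to 200 mm3 were randomly allocated to 1 of 2 arms. The first arm kept its estrogen (E2, 3 arrays). In the second, estrogen was withdrawn and tamoxifen, which blocks estrogen action at its receptor in breast cells, was given until the tumours grew again (TamR, 4 arrays). Tumours were collected at about 1000 mm3, and the labels call the arrays of an arm biological replicates. The comparison asks which transcripts separate tumours growing again under tamoxifen from tumours growing with estrogen. The TamR arm differs from the E2 arm in hormone, drug and outcome together, so the arrays compare the arms and not any of these alone.

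The arrays resembled each other in overall brightness, with a median intensity of 23.3, 24.1 and 23.1 for E2 1 to 3 and of 21.6, 24.1, 24.6 and 24 for TamR 1 to 4. Correlations of log2 intensity over the 14241 genes tested were 0.967 to 0.97 among E2 arrays and 0.957 to 0.977 among TamR arrays, against 0.922 to 0.958 between the arms. The first principal component held 44.2% of the variance and separated the arms. The intensity of the 3′ GAPDH control probe set over that of its 5′ partner, which rises with RNA degradation, was 0.932 to 0.987 on 6 arrays and 1.92 on TamR 1. The same ratio for ACTB was highest on TamR 1 as well, at 2.9, and was 1.33 to 2.24 on the other arrays. Bacterial control transcripts that are added to RNA before labelling gave signal on E2 3, TamR 3 and TamR 4 alone (dap 3′ probe set, 207 to 283, against 22.4 to 29.6 on the other 4 arrays). These 2 sets of arrays, which both hold both arms, are treated as labelling batches.

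GREB1, IGF1R, PGR and PDZK1, which are in the list of estrogen-induced genes, were among the 12 genes that fell most in TamR tumours. GREB1, an estrogen-induced growth regulator, had a log2 intensity of 10.57 ± 0.14 (SD, n = 3) in E2 tumours and lay at the floor on all 4 TamR arrays, which made it at least 95.1-fold lower (adjusted p = 3.81e-10). IGF1R, the insulin-like growth factor 1 receptor, fell from 9.31 ± 0.03 (SD, n = 3) to the floor on all 4 TamR arrays, at least 39.6-fold (adjusted p = 3.33e-09). PGR, the progesterone receptor, lay at the floor on 1 TamR array and was at least 24.5-fold lower (log2 difference −4.61 ± 0.25 SE, adjusted p = 2.39e-06), and the neuropeptide Y receptor NPY1R was 43.5-fold lower (−5.44 ± 0.25 SE, adjusted p = 4.29e-07). The apoptosis inhibitor BCL2, also at the floor on 1 TamR array, was at least 11.9-fold lower (−3.58 ± 0.26 SE, adjusted p = 1.55e-05). The other genes among the 12 that fell most were the scaffold protein PDZK1 (at least 27.8-fold), the matrix protein MGP (21.9-fold), the Rho GTPase-activating protein DLC1 (at least 21.8-fold), the psoriasin gene S100A7 (at least 16.4-fold), the protease PRSS23 (15.5-fold), the cytokine IL20 (at least 14.4-fold, at the floor on all 4 TamR arrays) and the protease inhibitor SERPINA3 (11-fold, adjusted p = 0.00521, log2 difference −3.46, and −4.08 without TamR 4). PDZK1, DLC1 and S100A7 each lay at the floor on 2 of the 4 TamR arrays.

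CRISP3, INHBB and ERBB4 were among the 12 genes that rose most in TamR tumours. CRISP3, a secreted cysteine-rich protein, lay at the floor on all 3 E2 arrays and reached 9.98 ± 1.58 (SD, n = 4) in TamR tumours, at least 63.3-fold higher (log2 difference 5.98, and 6.69 without TamR 4, adjusted p = 0.000212). INHBB, the inhibin and activin beta-B subunit, was 21.9-fold higher (log2 difference 4.45 ± 0.26 SE, adjusted p = 4.7e-06). ERBB4, a receptor tyrosine kinase of the epidermal growth factor receptor family, was 10.4-fold higher (3.37 ± 0.23 SE, adjusted p = 1.39e-05). The others were DSCR8 (14.2-fold), the epithelial keratin KRT13 (13.8-fold), CRYM (at least 12.4-fold), SPINK4 (at least 10.1-fold), RFTN1 (8.39-fold), the retinal dehydrogenase ALDH1A3 (at least 8.32-fold), the gel-forming mucin MUC2 (7.24-fold, adjusted p = 0.00163, log2 difference 2.86, and 2.17 without E2 1), SERHL2 (7.16-fold) and LRATD1 (at least 6.91-fold). SPINK4 lay at the floor on 2 E2 arrays and CRYM, ALDH1A3 and LRATD1 on 1. The probe sets of DSCR8 and SERHL2 are of a type that can also bind related transcripts, so those values may include a near-identical gene.

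Over all 14241 genes tested, limma called 938 genes at an adjusted p below 0.05, of which 603 were higher and 335 lower in TamR tumours. At least 2-fold differences made up 236 of the higher and 156 of the lower calls. The 2 arms did not overlap for 932 of the 938 genes, and they did not overlap for 19.3% of all genes tested, where chance gives 5.71%. With the labelling batch as a block 709 genes were higher and 460 lower. Within the 4 arrays without the control signal limma called 178 and 187 genes. Within the 3 arrays with it, of which 1 is an E2 array assumed to vary like the TamR arrays, it called 0 and 0, with 1986 genes at an unadjusted p under 0.05. Leaving out 1 array lowered the counts most without E2 1, to 270 higher and 170 lower, and gave 406 and 210 without E2 2, 384 and 208 without E2 3 and 410 and 255 without TamR 3. They were 237 and 163 when no dim genes were left out, 603 and 303 with the filter at the 60th percentile, and 80 and 64 with a floor of 64, at which the filter removed no gene.

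**Figure D1:**
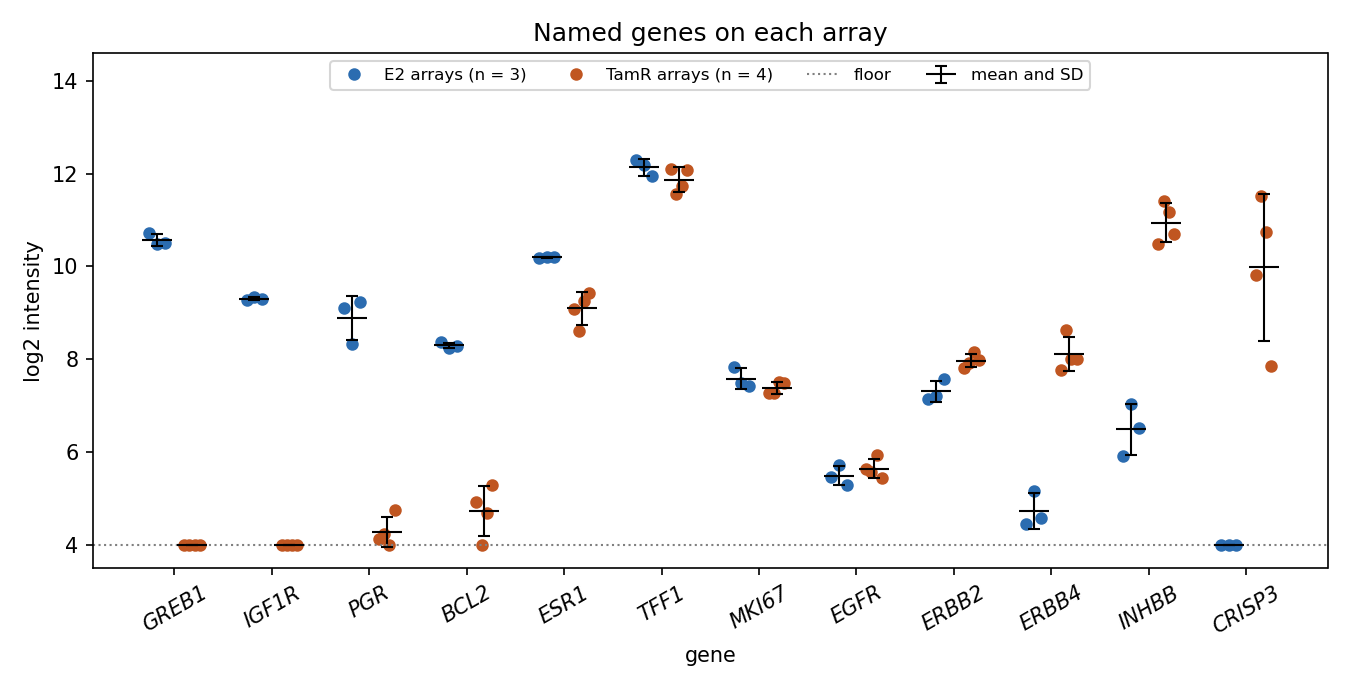
Log2 intensity (vertical axis) of 12 named genes on each array, with E2 arrays (n = 3) in blue, TamR arrays (n = 4) in orange, bars for the mean and SD, and a dotted line at the floor. GREB1 and IGF1R lay at the floor on all 4 TamR arrays and CRISP3 on all 3 E2 arrays, where an SD of 0 reflects the floor, while TFF1, MKI67 and EGFR overlapped between the arms.

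Genes that estrogen is known to induce in MCF-7 cells fell as a group, and genes that it is known to repress rose. Of 34 estrogen-induced genes tested, 22 fell, 2 rose and 10 did not pass the test, and the median log2 difference was −1.34 (camera adjusted p = 6.26e-24, and adjusted p = 0.174 with an estimated correlation). Adjusted over the list alone, 24 fell and 3 rose. Besides GREB1, IGF1R and PGR, the protein kinase A inhibitor PKIB was 10-fold lower (adjusted p = 3.98e-07). The 2 that rose were KRT13 and the disulfide isomerase AGR2 (3.14-fold, adjusted p = 0.0116, lost without E2 1 at 0.0747), the latter named after its value was seen. TFF1, a secreted trefoil peptide widely used as a marker of estrogen action, had a log2 intensity of 12.14 ± 0.18 (SD, n = 3) in E2 and 11.87 ± 0.26 (SD, n = 4) in TamR tumours, and did not pass the test (−0.27 ± 0.14 SE, adjusted p = 0.315). The highest value on an array was 12.20 to 12.63, and near it intensity can saturate, so a fall of TFF1 is not excluded.

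Of 15 estrogen-repressed genes tested, 10 rose, 0 fell by limma (11 and 0 at an unadjusted p under 0.05) and 5 did not pass, with a median log2 difference of 0.72 (camera adjusted p = 9.27e-08, and adjusted p = 0.042 with an estimated correlation). Adjusted over the list alone, 11 rose and 0 fell. BCAS1, a gene amplified in some breast cancers, was 6.08-fold higher (adjusted p = 0.000129), the pro-apoptotic BIK 3.11-fold (adjusted p = 0.00682), and the transcription factors KLF4 and BCL6 1.75-fold and 1.62-fold (adjusted p = 0.00705 and 0.00831). The shifts of both estrogen lists held within each labelling batch. The median was −1.67 and 0.74 over the arrays without the control signal and −0.94 and 0.53 over those with it, which hold 1 E2 array, against −1.35 and 0.70 with the batch as a block. The call of BIK was lost without E2 1 (adjusted p = 0.0506).

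**Figure D2:**
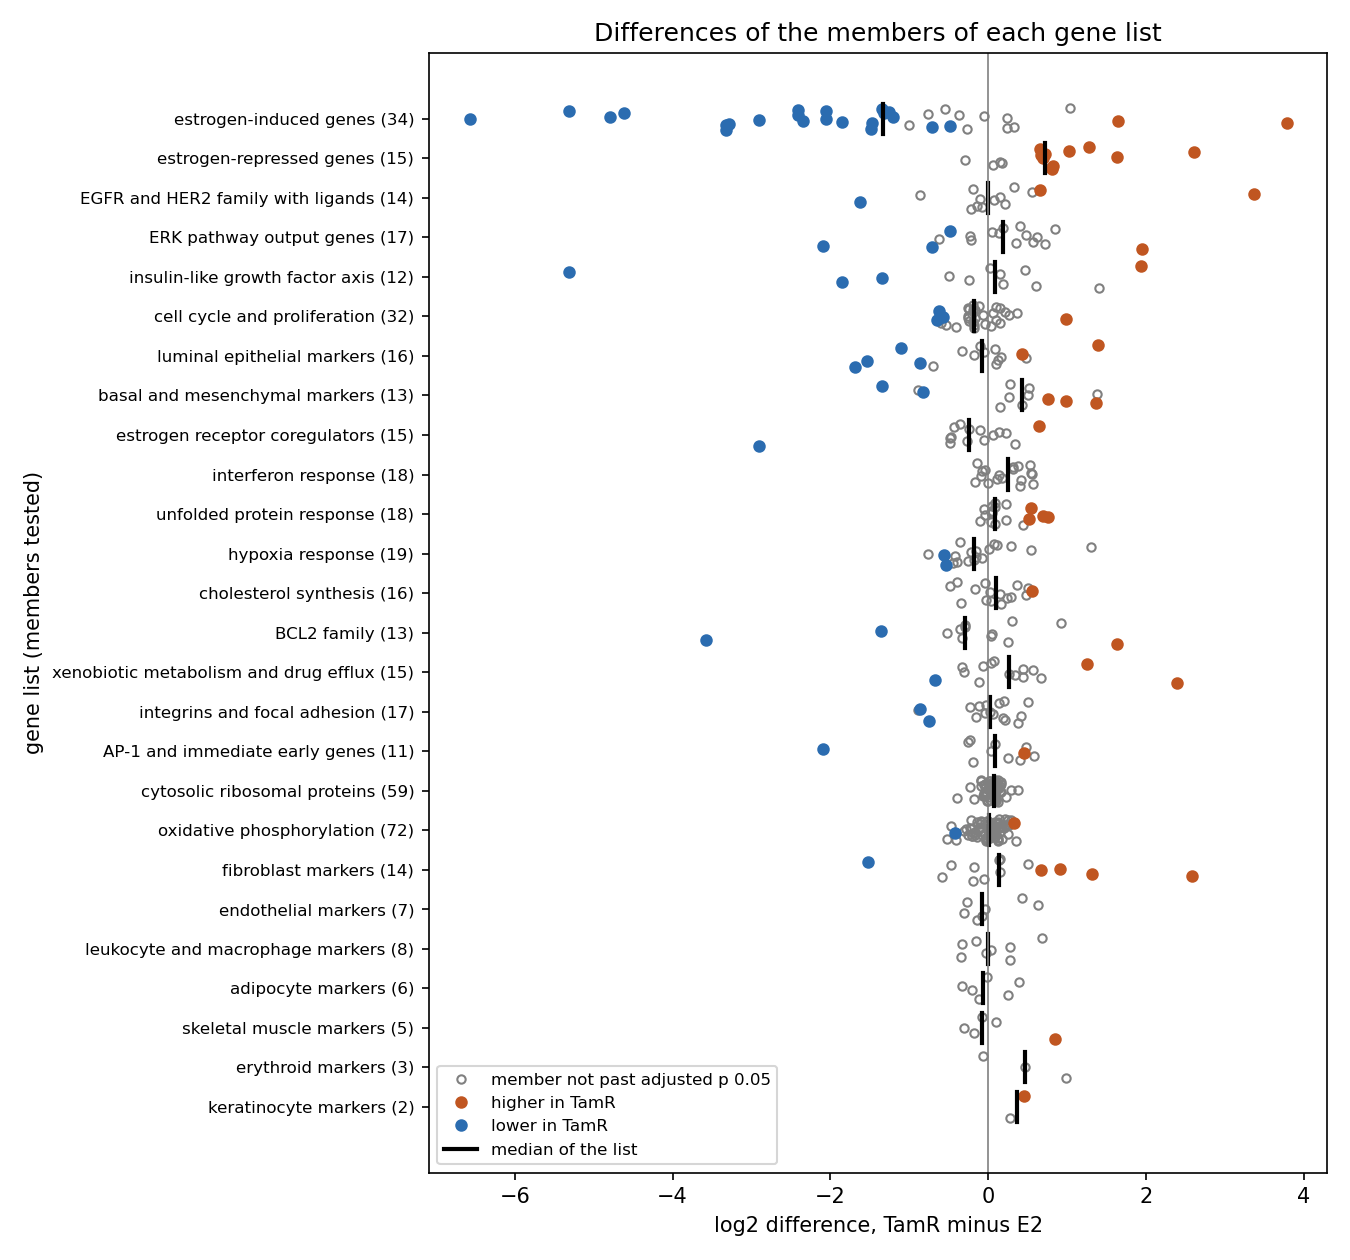
Log2 difference between TamR and E2 tumours (horizontal axis) of each tested member of the 26 gene lists, with members past an adjusted p of 0.05 filled (orange higher, blue lower), the others open, and a black bar at the median of each list. The median of the estrogen-induced list lay at −1.34 and that of the estrogen-repressed list at 0.72.

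Receptors of the epidermal growth factor family, their tested ligands and regulators did not shift in a common direction, and the members that changed went both ways. The list mixes receptors with genes that restrain them, so its median does not measure signalling through the family. Of 14 tested, 2 rose, 1 fell and 11 did not pass, with a median of 0.00 and a mean of 0.15 (camera adjusted p = 0.895). Adjusted over the list alone, 3 rose and 2 fell. ERBB4 rose as given above and ERBB2 (HER2) was 1.58-fold higher (7.97 ± 0.15, n = 4, against 7.31 ± 0.23, n = 3, SD, adjusted p = 0.0188), while LRIG1, which restrains these receptors, was 3.08-fold lower (adjusted p = 0.000162). EGFR (5.49 ± 0.21, n = 3, in E2 and 5.65 ± 0.21, n = 4, in TamR, SD) did not pass the test (adjusted p = 0.722), and the ligand TGFA had a log2 difference of −0.86 (adjusted p = 0.086, and 0.04 without E2 3). The call of ERBB2 was lost without E2 1, E2 2 or TamR 3 (adjusted p = 0.094, 0.0839 and 0.0623). The median of the list was −0.02 with the batch as a block, −0.02 within the arrays without the control signal and 0.09 within those with it, and leaving out 1 array moved it from −0.20 (without E2 2) to 0.14 (without E2 1).

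Genes that report the activity of the ERK kinases, which act downstream of these receptors, also went both ways. Of 17 tested, 1 rose, 3 fell and 13 did not pass, with a median of 0.19 (camera adjusted p = 0.965), and adjusted over the list alone 2 rose and 3 fell. IER3, an immediate early gene, was 3.88-fold higher (adjusted p = 7.29e-05). FOS, a subunit of the transcription factor AP-1, was at least 4.27-fold lower (adjusted p = 0.00057, at the floor on 1 TamR array), and the cell cycle regulators CCND1 and MYC, which are also in the estrogen-induced list, were 1.4-fold and 1.64-fold lower (adjusted p = 0.0389 and 0.0427). Of 11 AP-1 and immediate early genes tested, FOS fell, IER2 rose 1.37-fold (adjusted p = 0.0218) and 9 did not pass, with a median of 0.09 and a mean of −0.04 (camera adjusted p = 0.965), and adjusted over the list alone 1 rose and 1 fell. The calls of CCND1 and MYC lay near the threshold, and among the fits without 1 array CCND1 passed only without E2 3 or TamR 4 and MYC only without E2 3 (adjusted p up to 0.152 and 0.146 otherwise, and a MYC difference of −0.47 against −0.72 without E2 1). IER2 was lost without E2 1, E2 2 or TamR 3 (adjusted p = 0.0924, 0.0966 and 0.0657).

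In the insulin-like growth factor axis the receptor and its adaptor fell. IGF1R is described above, the adaptor IRS1 was 3.61-fold lower (adjusted p = 0.000767) and the binding protein IGFBP4 2.55-fold lower (adjusted p = 0.0075), while IGFBP5 was 3.82-fold higher (adjusted p = 0.00291). The other 8 of the 12 tested did not pass, and the median of 0.09 and the mean of −0.37 differed in sign (camera direction lower, adjusted p = 0.212, and fry adjusted p = 0.00536). With the mean of all probe sets of a gene the median was −0.24 (camera adjusted p = 0.0399, and 0.00899 to 0.611 over 24 settings of camera at the preset correlation). With an estimated correlation the list was not called (adjusted p = 0.703). Adjusted over the list alone, 2 rose and 4 fell. IGFBP4 was lost without E2 1 (adjusted p = 0.0557). Of 13 genes of the BCL2 family, which regulate apoptosis, the inhibitor BCL2 and the pro-apoptotic PMAIP1 (2.57-fold, adjusted p = 0.00363) fell, BIK rose and 10 did not pass, with a median of −0.29 (camera adjusted p = 0.3). Adjusted over that list alone, 2 rose and 2 fell. BIK was lost without E2 1 (adjusted p = 0.0506). BCL2L1 had a log2 difference of 0.93 and an adjusted p of 0.109.

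Genes of the S and M phases were slightly lower in TamR tumours. The median log2 difference of 32 genes tested was −0.18 (camera adjusted p = 0.0485, and adjusted p = 0.703 with an estimated correlation). Single members that passed were CCNB1 (1.56-fold lower, adjusted p = 0.0093), TOP2A (1.54-fold lower, adjusted p = 0.0195) and MCM7 (1.48-fold lower, adjusted p = 0.0147), which act in mitosis, chromosome unwinding and replication, and CCNE1, a cyclin of S phase entry, which was 1.98-fold higher (adjusted p = 0.00439). The other 28 did not pass, and adjusted over the list alone 1 rose and 4 fell. MKI67, a marker of cycling cells, had a log2 difference of −0.20 ± 0.14 (SE, adjusted p = 0.501). The call of the list was lost without E2 2 (−0.14, adjusted p = 0.163) or without TamR 2 (−0.10, adjusted p = 0.15), and the median was −0.18 with the batch as a block, −0.25 within the arrays without the control signal and −0.09 within those with it. CCNB1 was lost without E2 1 (adjusted p = 0.0575), MCM7 without E2 1 or E2 3 (0.0808 and 0.0519) and TOP2A without E2 2 or E2 3 (0.096 and 0.0806).

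Markers of luminal mammary epithelium changed singly. ESR1, the estrogen receptor itself, was 2.15-fold lower (10.21 ± 0.02, n = 3, in E2 and 9.10 ± 0.35, n = 4, in TamR, SD, adjusted p = 0.00209). The prolactin receptor PRLR was 3.22-fold lower (adjusted p = 0.000502) and the transcription factor TFAP2C 1.81-fold lower (adjusted p = 0.000703), while the mucin MUC1 was 2.63-fold higher (adjusted p = 2.42e-05). TFF3 (2.9-fold lower, adjusted p = 0.0358, lost without any 1 of the 3 E2 arrays or TamR 3, up to 0.136) and FOXA1 (1.34-fold higher, adjusted p = 0.0147, lost without any 1 of the 3 E2 arrays, up to 0.0571, and a difference of −0.28 with the mean of its probe sets) were named after their values were seen. In all, 4 of 16 fell, 2 rose and 10 did not pass, with a median of −0.08 (camera adjusted p = 0.212), and adjusted over the list alone 6 fell and 3 rose. Within the arrays without the control signal the median was −0.34 (adjusted p = 0.0437, over a range of 0.00346 to 0.703 in 26 settings), and over all 7 arrays adjusted p = 0.703 with an estimated correlation. Of 13 basal and mesenchymal markers, 3 rose, 2 fell and 8 did not pass, with a median of 0.43 (camera adjusted p = 0.212), and adjusted over the list alone 4 rose and 2 fell. P-cadherin, CDH3, was 2.59-fold higher (adjusted p = 0.00371), vimentin, VIM, 1.7-fold higher (adjusted p = 0.0243), and the adhesion receptor CD44 1.77-fold lower (adjusted p = 0.0215). FN1 was 2.53-fold lower (adjusted p = 0.0371, kept only without TamR 1, up to 0.157 otherwise) and TWIST1, named after its value was seen, 1.98-fold higher (adjusted p = 0.0445, kept only without TamR 2, up to 0.178 otherwise). VIM was lost without E2 1, E2 3 or TamR 3 (0.129, 0.0856 and 0.065) and CD44 without E2 1, E2 2 or TamR 3 (0.107, 0.0978 and 0.0641). Of 15 estrogen receptor coregulators, NRIP1, a corepressor that estrogen induces, was 7.5-fold lower (adjusted p = 0.00515), the coactivator NCOA1 was 1.57-fold higher (adjusted p = 0.0189, lost without E2 1 at 0.0878 and without E2 2 at 0.0804) and 13 did not pass, with a median of −0.24 (camera adjusted p = 0.212). Adjusted over that list alone, 1 rose and 2 fell.

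Most members of the stress and metabolic lists did not pass the test, where limma called 938 of all 14241 genes tested. Of 18 genes of the unfolded protein response 4 rose and 0 fell by limma (6 and 0 at an unadjusted p under 0.05), with 5 and 0 adjusted over the list alone and a median of 0.09 (camera adjusted p = 0.0685). The pseudokinase TRIB3 was 1.7-fold higher (adjusted p = 0.00444), though its other bright probe set differed by −0.305 (limma adjusted p = 0.454). The other 3 were HERPUD1, DNAJC3 and SEL1L (1.62-fold, 1.46-fold and 1.43-fold), each of which failed in 5 or more of the 7 fits that left out 1 array (adjusted p up to 0.107, 0.117 and 0.133). With the mean of its probe sets DNAJC3 had a difference of −0.08. The list passed fry (adjusted p = 0.0347), and camera without E2 1, TamR 1 or TamR 4 (adjusted p = 0.0482, 0.0447 and 0.0299, over a range of 0.0191 to 0.703 in 26 settings of camera or fry), but not with an estimated correlation (adjusted p = 0.703). Of 19 hypoxia-induced genes 0 rose and 2 fell by limma (2 and 5 at an unadjusted p under 0.05), with 0 and 3 adjusted over the list alone and a median of −0.18 (camera adjusted p = 0.0675). The list was called without E2 2, TamR 3 or TamR 4 (medians −0.26, −0.18 and −0.35, adjusted p = 0.00227, 0.045 and 0.0104), and with the batch as a block (−0.21, adjusted p = 0.0156), all at the preset correlation, and was not called with an estimated correlation (adjusted p = 0.793, over a range of 2.03e-06 to 0.793 in 26 settings). The median was −0.31 within the arrays without the control signal (adjusted p = 0.0408) and −0.16 within those with it, which hold 1 E2 array. The members that fell were P4HA2 (1.44-fold, adjusted p = 0.0167, lost without E2 1 at 0.0863 and E2 2 at 0.0547) and BNIP3 (1.48-fold, adjusted p = 0.0325, kept only without TamR 3 or TamR 4, up to 0.147 otherwise). The other bright probe set of P4HA2 differed by 0.303 (limma adjusted p = 0.571). Of 15 genes of xenobiotic metabolism and efflux 2 rose and 1 fell, as adjusted over the list alone, with a median of 0.26 (camera adjusted p = 0.42). The aryl hydrocarbon receptor AHR was 2.39-fold higher (adjusted p = 0.0184, lost without E2 1 at 0.103 and E2 2 at 0.0626), the glutathione transferase GSTP1 5.28-fold higher (adjusted p = 0.0418, kept only without TamR 2, up to 0.165 otherwise, with a log2 difference of 2.40, and 3.10 without TamR 2, whose log2 intensity of 4.92 lay near the E2 arrays) and TIPARP 1.6-fold lower (adjusted p = 0.0293, lost without E2 1, E2 2, TamR 2 or TamR 3, up to 0.136).

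Of 16 genes of cholesterol synthesis 1 rose and 0 fell by limma (5 and 1 at an unadjusted p under 0.05), with 2 and 0 adjusted over the list alone and a median of 0.09 (camera adjusted p = 0.389). It was IDI1 (1.47-fold, adjusted p = 0.024), which was lost without any 1 of the 3 E2 arrays (up to 0.0906). Its other bright probe sets differed by 0.486, −0.405 and −0.27 (limma adjusted p = 0.0841, 0.611 and 0.759). Over 24 settings its log2 difference ran from 0.09 to 0.64 (limma adjusted p up to 0.873). Of 17 integrin and focal adhesion genes 0 rose and 2 fell by limma (3 and 3 at an unadjusted p under 0.05), with 0 and 2 adjusted over the list alone and a median of 0.02 and a mean of −0.06 (camera adjusted p = 0.965). These were ITGA2 (1.83-fold, adjusted p = 0.0292) and ITGB5 (1.68-fold, adjusted p = 0.0404), and both were lost without any 1 of the 3 E2 arrays (up to 0.149 and 0.157), ITGA2 also without TamR 3 (0.0585) and ITGB5 also without TamR 1 (0.0514). Among 18 interferon-stimulated genes limma called 0 higher and 0 lower (3 and 0 at an unadjusted p under 0.05), as adjusted over the list alone, with a median of 0.25 (camera adjusted p = 0.212). At the preset correlation the list was called without E2 1 (0.54, adjusted p = 4.33e-09), and with an estimated correlation over all 7 arrays it was not (adjusted p = 0.976). On E2 1 ISG15 was brighter (10.96) than on E2 2 and E2 3 (10.16 and 9.89), and the median was 0.03 without E2 3. It was −0.07 within the arrays without the control signal and 0.74 within those with it, which hold 1 E2 array (adjusted p over a range of 1.59e-09 to 0.976 in 26 settings). ISG15 had a log2 difference of 0.56 (adjusted p = 0.145, and 0.00655 without E2 1). Among 59 cytosolic ribosomal protein genes it called 0 and 0 (1 and 2 at an unadjusted p under 0.05), as adjusted over the list alone (median 0.08, camera adjusted p = 0.389). Of 72 genes of oxidative phosphorylation 1 rose and 1 fell, as adjusted over the list alone (median 0.02, mean −0.00, camera adjusted p = 0.965). NDUFB9 was 1.25-fold higher (adjusted p = 0.0285, lost without any 1 array, up to 0.0931) and COX6C 1.34-fold lower (adjusted p = 0.0202, lost without E2 1, E2 2 or TamR 3, up to 0.103).

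Markers of other cell types were read because the tumours contain mouse tissue, whose RNA reaches human probes only in part. Of 14 fibroblast markers 4 rose and 1 fell, as adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.389, and fry adjusted p = 0.00215). The collagen genes COL5A2 and COL1A2 were 6.03-fold and 1.6-fold higher (adjusted p = 0.00341 and 0.00796) and the growth factor receptor PDGFRA 2.49-fold higher (adjusted p = 0.0118, lost without E2 1 at 0.0722 and E2 3 at 0.0503), while COL5A1 was 2.86-fold lower (adjusted p = 0.00489). COL3A1, named after its value was seen, was 1.88-fold higher (adjusted p = 0.0167, lost without E2 1 at 0.0583 and E2 3 at 0.0659). Limma called 0 and 0 of 7 endothelial, 8 leukocyte and macrophage, 6 adipocyte and 3 erythroid markers, as adjusted over the list alone in each case, with medians of −0.08, 0.00, −0.06 and 0.47 (camera adjusted p = 0.965, 0.943, 0.965 and 0.389). At an unadjusted p under 0.05 there were 1, 0, 0 and 1 markers, all of them higher. The globin HBB had a log2 difference of 0.99 (adjusted p = 0.154). Of 5 skeletal muscle markers MB rose 1.8-fold (adjusted p = 0.0103, lost without E2 1 at 0.0598) and 0 fell by limma (1 and 0 at an unadjusted p under 0.05), as adjusted over the list alone, with a median of −0.08 and a mean of 0.08 (camera adjusted p = 0.895). Of 2 keratinocyte markers tested KRT10 rose 1.38-fold (adjusted p = 0.0177, lost without E2 1, E2 3 or TamR 3, up to 0.073), as adjusted over the list alone, with a median of 0.37 (camera adjusted p = 0.212).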

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

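The tests of the labelling batch, of RNA quality, of single probe sets and of chromosome segments were chosen after the results they bear on were seen, while the comparison with other splits of the arrays was planned. The test of single probe sets was first counted over probe sets and then over genes, after its result was seen.

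The 938 genes that limma called between the arms were weighed against chance, batch and RNA quality. Of the 35 ways to split the 7 arrays into 3 and 4, only 1, the real split, called as many, and the highest of the others called 4. The other splits put both arms into 1 or both groups, which widens the spread within a group and lowers their counts. With 35 splits, this argues against chance but cannot exclude it. With the labelling batch as a block 918 of the 938 genes were still called, and with the ACTB 3′ to 5′ ratio as a covariate 834, which argues against either as the main source of the calls. Separation of the 12 highest genes within both batches was also tested, and is void because these genes were chosen as non-overlapping. Estrogen withdrawal, tamoxifen and regrowth remain open as candidate explanations, which the design does not separate and which were not tested.

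The 12 genes that fell most were weighed against a fault of 1 probe set and against loss of the chromosome segment that holds them. For 6 of them the array held another probe set with a mean log2 of 5 or more in E2 tumours, and for 5 of these 6 (GREB1, IGF1R, PGR, DLC1 and PRSS23) at least 1 such probe set was lower too (8 of the 10 probe sets), which argues against a fault of 1 probe set in those 5. For BCL2 the other bright probe set had a log2 difference of −0.00, and the remaining 6 genes had none, though MGP had 1 just below that limit (log2 difference −0.96, adjusted p = 0.015, at the floor on all 4 TamR arrays), so a fault of 1 probe set stays open for BCL2, NPY1R, PDZK1, S100A7, IL20 and SERPINA3. The median log2 difference of the 10 nearest tested neighbours (gene order of GRCh38.p14) was −0.126 or higher for each of the 12 genes, against −3.46 or lower for the genes themselves, which argues against loss of a segment that spans the neighbours. Loss of single genes, and lower transcription without estrogen as a hypothesis, may both account for the pattern and were not tested.

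Single TamR arrays lay far from the other 3 for 15 of the 167 values examined (8.98%). Chance gives about 5% for independent values that are not cut at a floor. Here some values lay at the floor, as for PDZK1 and S100A7, and list means share genes with single values. The excess over 5% is therefore not read as a result. On TamR 1, the GAPDH 3′ to 5′ ratio was 1.92 against 0.932 to 0.98. The log2 intensity of ALDH1A3 there was 7.42 against 7.07 to 7.09, that of PDZK1 5.08 against 4 to 4.15, that of S100A7 4.58 against 4 to 4.01 and that of FCER1G 6.57 against 5.05 to 5.26, and the mean of the adipocyte markers was 4.80 against 4.97 to 5.00. On TamR 2, INSIG1 was 8.91 against 8.55 to 8.59 and TIPARP 6.55 against 6.84 to 6.89. The mean of the ERK output genes on TamR 2 was 5.94 against 6.22 to 6.27, and that of the cell cycle genes 7.71 against 7.88 to 7.90. On TamR 4, KRT13 was 10.40 against 8.87 to 8.96, LRIG1 7.43 against 6.92 to 7.00, COL5A1 5.40 against 4.66 to 4.77, LAPTM5 4.72 against 5.14 to 5.18 and HOXC4 5.88 against 6.56 to 6.65.

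The control probe sets outside the comparison carried a signal of their own. The dap transcript, a bacterial RNA added before labelling, was 7-fold brighter on the dimmest of E2 3, TamR 3 and TamR 4 than on the brightest of the other 4 arrays. More mouse stroma in TamR tumours was also tested, through COL5A1 (log2 difference −1.52, against the higher values of other collagen genes), and that test was set aside after its result was seen, since how far mouse RNA reaches these probes is unknown.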

How the results depend on the processing

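The fits with the labelling batch, within the batches, with the ACTB ratio, and with no trend beside no filter or a floor of 64 were chosen after the data were seen. Of 92 called genes that are named, the sign held in 2200 of 2206 values over 24 settings and the threshold in 1632. The other values were 4 of 0 with a floor of 64 (TWIST1 and CEACAM7) and 2 of the other sign. The arms did not overlap for 932 of all 938 called genes, so fits on fewer of the same arrays could hardly turn a sign. The mean of all probe sets turned DNAJC3 (−0.081), FOXA1 (−0.28) and the median of the insulin-like growth factor list (−0.24). Counts of higher and lower genes were 80 and 64 with a floor of 64 (70 and 51 without a trend), and 237 and 163 with no filter (251 and 163 without a trend). Both settings tested 19775 genes, so the floor of 64 changed the floor and the genes tested together. They were 178 and 187 within the 4 arrays without the control signal, 0 and 0 by limma within the 3 with it (1986 at an unadjusted p under 0.05, with 1 E2 array), 236 and 156 at 2-fold and 965 and 529 at an adjusted p below 0.10. Leaving out 1 array gave 270 to 553 higher and 170 to 356 lower genes, fewest without E2 1. Other settings stayed within 1.5 times of 603 and 335. The estrogen-induced list (−1.34) lost its call only with an estimated correlation, among 26 settings (adjusted p 5.82e-37 to 0.174), and the estrogen-repressed list kept it in 26. Lists not called here were called in some of the 26 settings, hypoxia in 11, the unfolded protein response in 8, the insulin-like growth factor axis in 4, luminal markers in 3, the BCL2 family, coregulators and interferon in 2 each and fibroblast markers in 1. The cell cycle list lost its call with quantile normalisation (−0.157), median centring (−0.187), the mean of probe sets (−0.115), no trend (−0.184), an estimated correlation (−0.184), fry (−0.184), the ACTB ratio (−0.177) and within the 3 arrays with the control signal (−0.088), and leaving out 1 array gave −0.198 to −0.0999 (adjusted p 2.77e-07 to 0.703 over 26 settings). The 26 settings include camera with an estimated correlation and fry. Except where the number of arrays shows it, the cause was not tested. With the replicate number as a block 603 genes were higher and 463 lower. Deviations of same-numbered arrays correlated at 0.054, −0.19 and −0.027, and not every array correlated best with its own number, so the labels give only a number. The offset for log2 tables was not run, since the values are linear. Signal near the floor limits folds of the dimmest genes to bounds.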

Other observations

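The gene families in the first 2 paragraphs were chosen after the data were seen, and the list of apocrine and androgen-responsive genes was written after the 12 highest genes but before its own values were seen. Of these 9 lists 3 were called by camera at the preset correlation and 0 with an estimated correlation. Since the gene families were chosen with the data in view, their p-values are no independent support for a change. The 24 settings refit the same arrays, so the counts of settings below add no independent support either.

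Genes for replication-dependent histones, which package newly made DNA, were higher on balance in TamR tumours. Of 27 tested 4 rose and 0 fell by limma (10 and 0 at an unadjusted p under 0.05), with a median log2 difference of 0.52 (camera adjusted p = 0.000109 over 9 such lists, and adjusted p = 0.482 with an estimated correlation). H2BC4 was at least 3.88-fold and H1-2 3.69-fold higher (adjusted p = 0.00342 and 0.00261). The S and M phase genes had a median of −0.18, and their call was lost with an estimated correlation (camera adjusted p = 0.703). Whether the higher histone values reflect more DNA replication was not tested. How fully this labelling procedure reads histone transcripts was not examined either, so the values are not read as total histone output. The carcinoembryonic antigen genes and the neighbouring pregnancy-specific glycoprotein genes were higher on balance as well. Of 12 tested 5 rose and 0 fell by limma (6 and 0 at an unadjusted p under 0.05), with a median of 0.47 (camera adjusted p = 0.00339, and adjusted p = 0.365 with an estimated correlation). CEACAM6 was 5.42-fold, PSG9 at least 4.32-fold, CEACAM5 3.62-fold, PSG1 at least 3.12-fold and CEACAM7 at least 1.73-fold higher (adjusted p = 2e-04, 0.00128, 0.0075, 0.00267 and 0.0462, with CEACAM7 kept only without TamR 4, up to 0.133 otherwise). Both lists were called in 22 of 24 settings (medians 0 to 0.77 and 0 to 1.75, adjusted p up to 0.0951 in each). H2BC4, PSG9 and PSG1 lay at the floor on 2 of the 3 E2 arrays and CEACAM7 on all 3. Members of these families are alike in sequence, so their probe sets can share signal.

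The homeobox genes of the HOXC cluster, which set position along the body axis, were lower on balance. Of 9 tested 3 fell, 1 rose and 5 did not pass, with a median of −0.32 (camera adjusted p = 0.00946, called in 24 of 24 settings with adjusted p up to 0.043 and medians −0.78 to 0, and adjusted p = 0.25 with an estimated correlation). Without TamR 3 the median was −0.20. HOXC6 was 2.67-fold, HOXC10 1.79-fold and HOXC4 1.72-fold lower (adjusted p = 0.0105, 0.000571 and 0.0372) and HOXC13 1.87-fold higher (adjusted p = 0.0271). HOXC6 was lost without E2 2 (0.0603), HOXC4 without any 1 of the 3 E2 arrays (up to 0.132) and HOXC13 without E2 1, E2 3, TamR 2 or TamR 3 (up to 0.109). Of 8 HOXB genes 1 rose and 0 fell by limma (1 and 1 at an unadjusted p under 0.05, median 0.15, camera adjusted p = 0.623). Keratins, serpins, mucins with trefoil factors and MAGE genes were not called as lists in the fit to all 7 arrays (medians 0.07, −0.16, 0.02 and 1.01, camera adjusted p = 0.33, 0.243, 0.69 and 0.253). Of 24 settings MAGE genes were called in 3 (adjusted p from 0.000605 to 0.983), serpins in 2 (0.0466 to 0.941), keratins in 1 (0.0413 to 0.726) and mucins in 0 (0.324 to 0.958). Leaving out 1 array gave MAGE medians of 0.56 without TamR 2 to 1.49 without TamR 4, keratin medians of −0.06 without E2 2 to 0.20 without E2 1 and serpin medians of −0.27 without E2 3 to 0.00 without E2 1. For mucins with trefoil factors it gave −0.10 without E2 2 to 0.17 without E2 1.

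CRISP3, among the 12 genes that rose most, is made in exocrine glands, and an apocrine and androgen-responsive program was tested as a hypothesis. In the 13 tested genes of a list of 23, none of them among the 12, the median log2 difference was 0.16 (camera adjusted p = 0.852), below the 0.2 set beforehand. Their differences ran from −1.01 (FKBP5, lower) to 1.17 (ALCAM, higher), against 2.79 for the lowest of the 12 genes. By the rule set beforehand, a median at or below 0.2 went against the hypothesis. Leaving out 1 array, which that rule did not ask for, moved the median from 0.05 (without TamR 3) to 0.28 (without E2 2). The list was called in 0 of 24 settings (adjusted p 0.474 to 0.966). Only because the median lay on both sides of 0.2 in the fits without 1 array is the hypothesis left open.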
